A study of Homo sapiens with 4 samples.

How the data were processed

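Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and leaves sequencing adapters there, in human cells. Per the labels, 2 libraries came from neural stem cells (NSC) and 2 from embryonic stem cells (ESC). Permeabilised nuclei were treated with the transposase, and the amplified DNA was sequenced on a HiSeq 2500 with paired ends, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, HTSeq 0.12.4, edgeR, Picard, deepTools 3.4.3, MACS2 2.1.2 and bedtools 2.30.0, without saying which step each served, and the genome builds GRCh38 and hg38. The peak calling parameters, the shift of cut sites, the removal of duplicate reads and any list of excluded regions are not given in the sources used here. Each of these steps can change how many peaks a library has.

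The authors deposited a peak list for each library and an interval set for each cell type. Peaks were called in each library separately, and one interval can carry several summits. The deposited values on the −log10 scale are the peak caller's p and q of each summit within its own library, and the lowest −log10 q in the lists was 1.30, which is a q of 0.05. The deposited fold enrichment is the height of a summit over the local background of the same library, as the layout of the lists gives it. The deposited score is the −log10 q multiplied and cut to a whole number. The lists also give the distance from the start of an interval to its summit. These values are the authors' own and were used to describe, rank and filter the peaks of each list. Their medians, and shares past a q threshold, are given per library to describe the lists and depend on depth, so they are no measure of a change in accessibility between labels. The interval set named for ESC carries a deposited value per interval that equals the mean fold enrichment of the overlapping summits of both libraries labelled NSC in 83.8% of its 84955 autosomal intervals, with a tolerance of 0.001. The set named for NSC pairs a peak of one library with an overlapping peak of another.

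The files hold no read counts, so the sequencing depth of each library is unknown and no counting interval can be given. The number of peaks a library yields depends on its depth and its background as well as on its chromatin. A region without a peak in a library is therefore a region where none was called, not one shown to be closed. The labels do not say that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, or between regions and genes within them, which may be technical.

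Samples were grouped by their titles. The names inside the peak lists carry the other cell type in 4 of 4 libraries, so groups are called labelled NSC and labelled ESC throughout, and every direction refers to the label. Peaks on the autosomes were merged across the 4 libraries wherever they overlapped by at least 1 bp. A merged region was called specific to a label when both of its libraries and neither library of the other label had a peak in it, and common when all 4 had one. Chromosomes X and Y and unplaced contigs were not used here. The similarity of libraries was measured by the Jaccard index, the bases covered in both divided by the bases covered in either.

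Gene positions came from the RefSeq annotation of assembly GRCh38.p14, the build of the files, as the start and end of each gene. The table used gives neither strand nor exons. Windows planned around transcription start sites were therefore placed around both ends of each gene, and exons and introns were replaced by 3 classes: a summit within 1 kb of a gene end, a summit elsewhere inside a gene, and an intergenic summit. A gene end can be the start or the end of the transcript. No genome sequence was used here, so the 22 planned motif strings were not searched.

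For each of 19126 protein-coding autosomal genes, regions with their midpoint within 50 kb of either gene end were counted. Genes with at least 5 label-specific regions were tested by Fisher's exact test, two-sided, of NSC-only and ESC-only regions inside the window against those elsewhere, with Benjamini-Hochberg adjustment and a threshold of 0.05. The log2 odds carry a prior count of 0.5. Neighbouring genes share regions, and regions rather than cultures are the unit of this test.

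There were 15 gene lists: pluripotency, neural stem and progenitor, genes shared by both cell types, forebrain, midbrain to spinal cord, HOX, neuron, glia, neural crest and mesenchyme, endoderm and mesoderm, Notch, WNT, FGF with TGF-beta and Hedgehog signalling, cell adhesion, and housekeeping. Of their 343 genes, 341 were matched, while HPRT1 and PGK1 lie on chromosome X. TDGF1 was matched under its symbol CRIPTO and C1orf43 under LTAP1. The share of NSC-only regions at the loci of a list was set against 10000 random lists of as many genes, matched on the number of label-specific regions per gene, by a two-sided permutation test. Gene ends with a peak in both libraries of one label only were compared with all other genes by Fisher's exact test, two-sided, over 30 tests. Both families were adjusted by Benjamini-Hochberg.

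The named genes are 10 identity genes, and in each list the members with the most NSC-only minus ESC-only regions and those with the most ESC-only minus NSC-only regions, whether called or not. The per-gene test would have added its called genes with the smallest adjusted p in each direction, but it called none. Samples, tests, lists, named-gene rule and alternatives were fixed before the data were examined. The exceptions are the changes given above, the alternatives named in the closing section as added later, and the test of exchanged labels.

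Results were recomputed with peaks of −log10 q at least 5, with the strongest 40188 intervals of each library (equal numbers), without each library in turn, with reciprocal overlap of 50%, with windows of 500 bp around summits, with gene windows of 10 kb and 100 kb, with no minimum of regions, with gene ends of 500 bp and 2500 bp, and with the replicate number as a block. Equal numbers drop the weaker intervals of the longer lists. In that setting a region or gene end specific to the ESC label can therefore hold a weaker called peak under the NSC label. The per-gene test was tested on simulated data over 10234 genes. Genes were planted only where the window held more label-specific regions than the median tested window, which held 7. Recovery in smaller windows was not measured. The test recovered 4 of 100 genes planted with an odds ratio of 4 and 36 of 100 with an odds ratio of 16, and called 0 of 9328 others. In the direction of the NSC label it recovered 0 at either odds ratio, so a count of 0 in that direction carries no information. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0.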

Results

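The accessible chromatin of human neural stem cells and human embryonic stem cells was compared in 4 ATAC-seq libraries, 2 labelled NSC and 2 labelled ESC. Embryonic stem cells are pluripotent, able to form every tissue of the body, and neural stem cells are already committed to the nervous system. The libraries labelled NSC held 148438 and 149698 peak intervals, and those labelled ESC held 41407 and 44105. Their median interval widths were 307 and 311 bp under the NSC label, and 256 and 283 bp under the ESC label. The authors' median fold enrichment per summit was 5.29 and 5.53 in the libraries labelled NSC and 3.92 and 4.41 in those labelled ESC. An interval had a −log10 q of at least 5 in 72.2% and 74.2% of cases under the NSC label, and in 38.6% and 53.6% under the ESC label. Sequencing depth is unknown for all 4 libraries.

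The identity of the cells was examined first, because the titles of the samples and the names inside their peak lists give different cell types in 4 of 4 libraries. Pluripotency genes carried more regions with a peak under the NSC label than under the ESC label, as did the autosomes as a whole. Of all merged regions, 141287 ± 1172 had a peak in a library labelled NSC and 39470 ± 1758 in one labelled ESC (SD, n = 2). That is a ratio of 3.58. The ratio was above this at POU5F1 (11), NANOG (19), L1TD1 (24) and DPPA4 (5.0), and below it at LIN28B (3.38). POU5F1, which encodes the pluripotency factor OCT4 (chromosome 6, 31164337 to 31170682, GRCh38), had 16.5 ± 2.12 regions within 50 kb of its ends in the libraries labelled NSC and 1.5 ± 0.707 in those labelled ESC (mean ± SD, n = 2). NANOG, another core pluripotency factor (chromosome 12, 7789402 to 7799146), had 9.5 ± 2.12 and 0.5 ± 0.707 regions, and L1TD1, an RNA-binding protein of undifferentiated cells (chromosome 1, 62194849 to 62212328), had 12.0 ± 2.83 and 0.5 ± 0.707 (n = 2 each). DPPA4 (chromosome 3, 109326144 to 109339636) had 7.5 ± 2.12 and 1.5 ± 0.707 regions, and LIN28B, an inhibitor of let-7 microRNA maturation (chromosome 6, 104937026 to 105083332), had 13.5 ± 2.12 and 4.0 ± 0 (n = 2 each).

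Genes of neural stem cells also had more regions under the NSC label, by amounts that varied between genes. Their ratios lay below the 3.58 over all merged regions at SOX1 (1.71), POU3F2 (1.91), PAX6 (3.43) and FABP7 (3.5). At LHX2 the ratio was above it (8.33). SOX1, an early neural transcription factor (chromosome 13, 112067149 to 112071706), had 12.0 ± 1.41 regions under the NSC label and 7.0 ± 1.41 under the ESC label, and POU3F2, a neural POU factor (chromosome 6, 98834574 to 98839458), had 10.5 ± 0.707 and 5.5 ± 0.707 (n = 2 each). FABP7, the brain fatty acid binding protein of radial glia (chromosome 6, 122749201 to 122784074), had 10.5 ± 0.707 and 3.0 ± 0 regions. PAX6 (chromosome 11, 31789026 to 31817961) had 12.0 ± 0 and 3.5 ± 0.707, and LHX2 (chromosome 9, 124011768 to 124033301), a forebrain and eye field factor, had 12.5 ± 0.707 and 1.5 ± 0.707 (n = 2 each). Once each library was given the same number of peaks, POU5F1 had 3 NSC-only and 0 ESC-only regions, NANOG 2 and 0, L1TD1 3 and 0, DPPA4 2 and 0 and LIN28B 1 and 1. Under that setting SOX1 had 1 and 3 and POU3F2 0 and 3, while PAX6 had 2 and 0, LHX2 1 and 0 and FABP7 0 and 0.

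**Figure D1:**
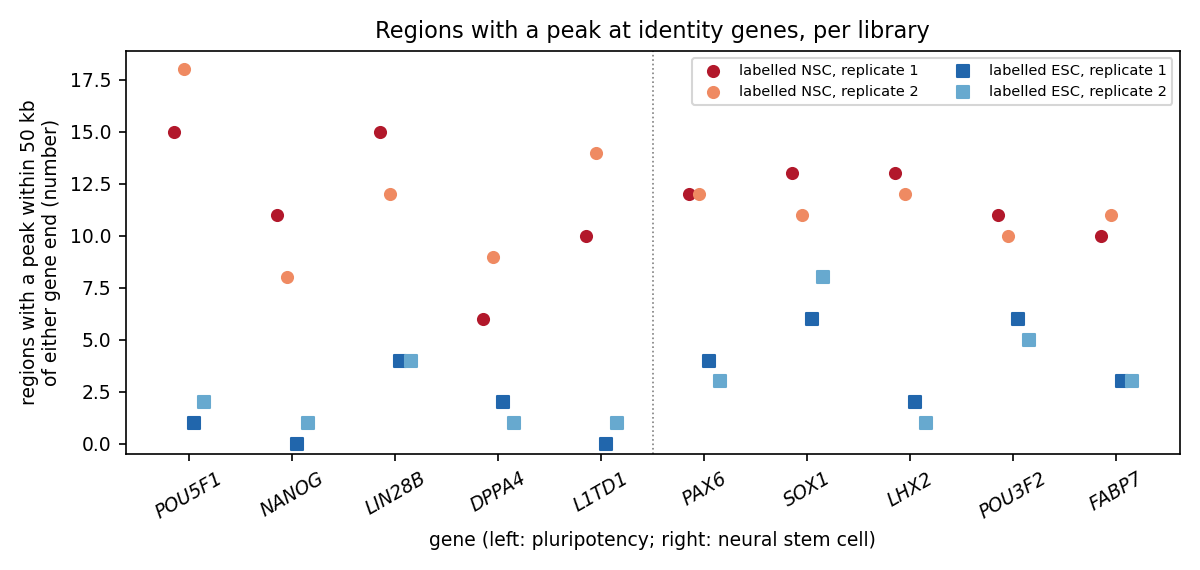
Number of regions with a peak within 50 kb of either end of each of 10 identity genes, with 1 point per library; circles are the libraries labelled NSC and squares those labelled ESC, and the genes left of the dotted line are pluripotency genes. At NANOG the libraries labelled NSC had 11 and 8 regions and those labelled ESC 0 and 1, while at SOX1 the values were 13 and 11 against 6 and 8.

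As a share of all regions with a peak in a library, the 33 pluripotency loci took 0.267% ± 0.00329 under the NSC label and 0.232% ± 0.00939 under the ESC label (SD, n = 2), a ratio of 1.15. The 34 neural stem and progenitor loci took 0.334% ± 0.00627 and 0.439% ± 0.0195, a ratio of 0.761. The libraries of the groups did not overlap in either share. These ratios were 1.58 and 0.729 with equal numbers of peaks. The share at pluripotency loci was higher under the NSC label, and the share at neural stem and progenitor loci was higher under the ESC label. Other neural lists went the other way or differed little: the ratio of shares was 1.3 for forebrain, 1.40 for midbrain to spinal cord, 0.985 for neuronal and 1.07 for glial loci, and 1.46, 1.31, 1.36 and 1.32 with equal numbers of peaks. Reference and signalling lists moved too. With all peaks the ratio was 0.578 for housekeeping, 0.793 for WNT, 0.804 for Notch and 0.813 for FGF, TGF-beta and Hedgehog loci. In that setting a ratio below 1 was thus not specific to neural loci. A ratio above 1 was not specific to pluripotency loci either, with 3.19 for HOX, 1.18 for endoderm and mesoderm and 1.14 for neural crest and mesenchyme loci (1.60, 1.07 and 0.939 at equal peak numbers). With equal numbers of peaks the ratio was 1.09 for housekeeping, 0.865 for WNT, 0.909 for Notch and 1.04 for FGF, TGF-beta and Hedgehog loci. The ratio at neural stem and progenitor loci (0.729) was then the lowest of the lists. Only the HOX ratio, from 13 and 17 regions against 9 and 9, lay above that at pluripotency loci (1.58). No test was made of these shares.

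The authors' interval sets for each cell type carried names opposite to the titles of the libraries they matched. All 87915 intervals of the set named for ESC overlapped a peak in both libraries labelled NSC (100%), while 21.2% and 26.4% overlapped a peak in the libraries labelled ESC. The set named for NSC had 20234 distinct first intervals, and 100% of them were identical to an interval of ESC replicate 1. Its 19777 distinct second intervals were all identical to intervals of ESC replicate 2 (100%). Of the first intervals, 86.1% and 86.2% overlapped a peak of NSC replicates 1 and 2. Groups follow the titles here, and every direction holds for the label and not necessarily for the cell type.

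The comparison of peak number asks how much of the genome was called as peaks under each label, which also depends on depth and background. The libraries labelled NSC had 169218 ± 1752 summits and those labelled ESC 46573 ± 3190 (SD, n = 2), 3.63 times as many. Intervals numbered 149068 ± 891 and 42756 ± 1908, a ratio of 3.49, and the autosomal sequence they covered was 55.3 ± 0.952 Mb and 13.9 ± 1.70 Mb. The differences exceeded the spread between replicates, but 2 libraries per label cannot reach significance, and the exact permutation test, two-sided, gave p = 0.333, the smallest that 6 permutations allow. With peaks of −log10 q at least 5, the ratio of intervals was 5.51.

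By the Jaccard index, replicates resembled each other more than libraries of the other label. The Jaccard index was 0.546 between the libraries labelled NSC and 0.317 between those labelled ESC, and ranged from 0.122 to 0.166 across labels (mean 0.144 ± 0.0241, SD over the pairs). The mean within labels exceeded that between labels by 0.287, and 1 of the 3 splits into pairs gave so large a difference (exact permutation p = 0.333, one-sided, the smallest possible). Of the intervals of ESC replicates 1 and 2, 53.6% and 61.6% overlapped a peak of NSC replicate 1, whereas 14.1% and 17.5% of the intervals of NSC replicate 1 overlapped a peak of ESC replicates 1 and 2. Fewer of the intervals of ESC replicates 1 and 2, 49.1% and 45.0%, overlapped the other ESC replicate. With equal numbers these values were 48.6% and 47.4%, against 39.6% and 45.8% that overlapped NSC replicate 1. The Jaccard index was then 0.635 and 0.325 within the NSC and ESC labels, and 0.203 to 0.265 across labels. Without NSC replicate 1 or 2, the difference in Jaccard index was 0.174 and 0.172.

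Label-specific regions were far more numerous under the NSC label. Of 211047 merged autosomal regions, 75033 had a peak in both libraries labelled NSC only, 2179 in both labelled ESC only, and 15573 in all 4. NSC-only regions made up 73.9% of the 101582 regions found in both libraries labelled NSC, while ESC-only regions made up 11.7% of the 18631 found in both labelled ESC. Pairing 1 library of each label gave 601 to 817 regions specific to the pair. Median widths were 381 bp for NSC-only, 374 bp for ESC-only and 819 bp for common regions.

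The imbalance depended on the number of peaks used. With equal numbers of peaks, 15585 regions were NSC-only, 4897 ESC-only and 12252 common, so the NSC-only share of label-specific regions was 76.1% in place of 97.2%. Without ESC replicate 1 or 2, a single library sufficed and ESC-only regions numbered 14977 and 17399, and without NSC replicate 1 or 2, NSC-only regions numbered 115616 and 114318.

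Common regions lay at gene ends far more often than label-specific ones. Each region was placed by its strongest summit in replicate 1 of its label, and common regions by that in NSC replicate 1. This summit lay within 1 kb of a gene end in 54.0% of common, 6.46% of NSC-only and 2.94% of ESC-only regions. Regions inside genes made up 25.2%, 45.6% and 45.6%, and intergenic regions 20.8%, 47.9% and 51.5%. ESC-only and common regions differed in the share inside genes (adjusted p = 9.64e-81) and in the intergenic share (adjusted p = 4.13e-187, Fisher's exact test, two-sided, 9 tests). Between NSC-only and ESC-only regions the gene-end share differed by 3.52 points (adjusted p = 3.56e-13) and the intergenic share by -3.55 points (adjusted p = 0.00124), and the share inside genes did not differ detectably (adjusted p = 1.0). Both differences changed sign with equal numbers of peaks, to -3.33 points at gene ends (adjusted p = 1.43e-12) and 3.81 points in intergenic regions (adjusted p = 3.80e-06). Per library, 12.7% ± 0.0956 of autosomal intervals had their strongest summit at a gene end under the NSC label and 27.9% ± 0.830 under the ESC label (SD, n = 2).

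Gene ends with a peak were also more often specific to the NSC label than to the ESC label. Of 19126 genes, 9602 had a peak at a gene end in all 4 libraries, 2560 only under the NSC label and 34 only under the ESC label. The 34 genes included ZIC2, a zinc-finger factor of the developing brain, and, chosen after their values were seen, the Eph receptor EPHA6 and the oligodendrocyte precursor receptor GPR17. ZIC2 was their only member of a fixed list. The rest also included A2M, CPA1, PI16 and TPSG1, and no theme among the 34 was tested. The counts were 8659, 840 and 485 with equal numbers of peaks.

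Among the pluripotency genes, 13 of 33 had a gene-end peak only under the NSC label (39.4%), against 13.3% of other genes (adjusted p = 0.00269, Fisher's exact test, two-sided). They were CDH1, CRIPTO, DPPA2, DPPA3, DPPA4, EPCAM, FGF4, FOXH1, GDF3, L1TD1, NANOG, TFCP2L1 and UTF1. DNMT3B, a DNA methyltransferase, and PRDM14 were among the 7 with a peak in all 4 libraries, and 0 of 33 had one only under the ESC label. At equal peak numbers, 8 of 33 (24.2%) against 4.36% of other genes had a peak only under the NSC label (adjusted p = 0.00210). With gene ends of 500 bp the adjusted p was 0.0875.

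Of the 34 neural stem and progenitor genes, 20 had a gene-end peak in all 4 libraries (15 at equal peak numbers), among them SOX1, NES, VIM and POU3F2, while MSI1, NR2F2 and SLC1A3 had one only under the NSC label (3 of 34, adjusted p = 1.0) and 0 only under the ESC label. When peak numbers were equal, DACH1, DLL1, MEIS2, NR2F1 and SOX21 had a peak only under the ESC label, 5 of 34 (14.7%) against 2.51% of other genes (adjusted p = 0.0173, Fisher's exact test, two-sided). With all peaks, these 5 genes had a gene-end peak in all 4 libraries. Their peaks under the NSC label were thus called but fell outside the strongest intervals kept.

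Lineage genes of other cell types also had gene-end peaks only under the NSC label more often than other genes. These were 8 of 17 forebrain genes, including EMX1 (adjusted p = 0.00766), and 8 of 22 midbrain to spinal cord genes, including PAX7 and EN1 (adjusted p = 0.0285). They were also 13 of 33 HOX genes (adjusted p = 0.00269), 7 of 14 glial genes, including the myelin gene MBP and the water channel gene AQP4 (adjusted p = 0.00766), and 8 of 18 endoderm and mesoderm genes, including SOX17 and TBXT (adjusted p = 0.00766, Fisher's exact test, two-sided). At equal numbers none of these 5 lists passed: the adjusted p was 0.413 for glia and 0.951 for the other lists, and 0 HOX and 0 midbrain to spinal cord genes had an NSC-only peak. The midbrain to spinal cord call also ended without NSC replicate 1 (adjusted p = 0.0604) and with stricter peaks (0.372), the HOX call with stricter peaks (0.131), and the glial call without ESC replicate 2 (0.0682). The forebrain call ended with gene ends of 2500 bp (adjusted p = 0.113) and the endoderm and mesoderm call with 500 bp (0.196).

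The other lists did not pass at gene ends. NSC-only peaks were found at 6 of 24 neuronal genes (adjusted p = 0.370), 6 of 20 neural crest and mesenchyme genes (0.157), 4 of 21 Notch genes (1.0), 5 of 28 WNT genes (0.966), 6 of 31 genes of FGF, TGF-beta and Hedgehog signalling (0.805), 6 of 24 adhesion genes (0.370), 2 of 29 housekeeping genes (0.966) and 0 of 8 genes shared by both cell types (1.0). Of the housekeeping genes, 24 of 29 had a gene-end peak in all 4 libraries, and the number was 24 with equal numbers of peaks too. ZIC2 was the 1 shared gene of 8 with an ESC-only gene-end peak (adjusted p = 0.0606), and with stricter peaks this list passed (adjusted p = 0.0396). Neural crest and mesenchyme genes passed toward the NSC label without ESC replicate 1 (adjusted p = 0.00864) and with gene ends of 2500 bp (0.0226). When peak numbers were made equal, the Notch genes DLL1, MAML3, NOTCH3 and NRARP had an ESC-only peak (4 of 21, adjusted p = 0.0173), and the adhesion genes CDH1, CLDN3, CLDN6, CNTN2 and EPCAM an NSC-only peak (5 of 24, adjusted p = 0.0256, Fisher's exact test, two-sided). With all peaks, these 4 Notch genes had a gene-end peak in all 4 libraries, while the 5 adhesion genes had one only under the NSC label. Adhesion genes also passed toward the NSC label with stricter peaks (adjusted p = 0.00433) and without ESC replicate 2 (0.00392).

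Single loci were then compared with the genome's own balance of 97.2% NSC-only regions. None of the 10234 genes tested was called in either direction by Fisher's exact test with Benjamini-Hochberg adjustment, and at an unadjusted p under 0.05 there were 0 toward the NSC label and 142 toward the ESC label. The test could not make a call toward the NSC label, since its smallest adjusted p there was 1. Without NSC replicate 1 there was 1 call toward the ESC label, at LOC124905368, and without ESC replicate 2 there were 3, at TPTE, TTC34 and LOC124903442, all named after their values were seen. Equal numbers of peaks left 777 genes to test, of which 0 were called, with 0 and 24 at an unadjusted p under 0.05.

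At WNT pathway loci the share of NSC-only regions was lower than at matched loci. The 28 genes had 172 NSC-only and 13 ESC-only regions (93.0%, adjusted p = 0.00900, two-sided permutation test against 10000 random lists). FZD2, a WNT receptor (chromosome 17, 44557484 to 44561262), had 4 NSC-only and 2 ESC-only regions, with 13.0 ± 0 regions per library under the NSC label and 10.0 ± 1.41 under the ESC label (SD, n = 2). The transcription factor gene TCF7L1 (chromosome 2, 85133392 to 85310387) had 16 and 0, the ligand gene WNT4 11 and 0, and the inhibitor gene DKK1 0 and 0. Of the 23 WNT genes tested singly, 0 were called over all genes tested and 1, WNT7B, adjusted over the list alone, with 6 NSC-only and 3 ESC-only regions (p = 0.00166, Fisher's exact test, two-sided). The WNT call ended without ESC replicate 1 (adjusted p = 0.458), without ESC replicate 2 (0.897), with stricter peaks (0.400) and with windows of 10 kb (0.672), and held with equal numbers of peaks (30 and 24 regions, 55.6%, adjusted p = 0.00450). Fisher's exact test, two-sided, on distinct regions gave an adjusted p of 0.0367.

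Neural stem and progenitor loci had 228 NSC-only and 12 ESC-only regions (95%, adjusted p = 0.0590, permutation test), which did not pass. With equal numbers of peaks they had 40 and 43 (48.2%), against a median of 79.5% in random lists, and passed (adjusted p = 0.00300). Regions counted as ESC-only in that setting can hold a weaker called peak under the NSC label. Without NSC replicate 1, NSC replicate 2 and ESC replicate 2 the adjusted p was 0.0130, 0.00900 and 0.0190, and with stricter peaks 0.0150. It was 0.691 without ESC replicate 1, 0.624 with windows of 10 kb and 0.172 with 100 kb, and 0.370 by Fisher's exact test, two-sided, on distinct regions (5.83e-07 at equal peak numbers). The neural cadherin gene CDH2 (chromosome 18, 27932879 to 28177130) had 10.5 ± 3.54 and 7.0 ± 1.41 regions under the NSC and ESC labels, and DACH1 had 8.5 ± 2.12 and 6.5 ± 2.12 (SD, n = 2). MEIS2 had 20.5 ± 3.54 and 5.5 ± 0.707 regions, and NFIX 29.5 ± 0.707 and 7.0 ± 4.24 (n = 2).

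Pluripotency loci had 218 NSC-only and 4 ESC-only regions (98.2%, adjusted p = 0.938, permutation test) and did not differ detectably from matched loci. With equal numbers of peaks they had 64 and 8 (88.9%, adjusted p = 0.126, and 0.0416 by Fisher's exact test, two-sided, on distinct regions), and without ESC replicate 1 the adjusted p was 0.0210. CDH1, the epithelial cadherin (chromosome 16, 68737292 to 68835537), had 19.0 ± 0 regions under the NSC label and 1.5 ± 0.707 under the ESC label, and FOXH1, a partner of SMAD proteins in NODAL signalling, had 23 ± 0 and 5.5 ± 3.54 (SD, n = 2). LEFTY1, a NODAL antagonist, had 10.5 ± 0.707 and 5.5 ± 0.707, and SALL4 6.5 ± 0.707 and 3.0 ± 0 (n = 2).

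HOX loci, which pattern the body axis, had 70 NSC-only and 0 ESC-only regions (100%, adjusted p = 0.0285, permutation test). HOX genes share their windows, and Fisher's exact test, two-sided, on their distinct regions, chosen after the data were seen, did not pass (adjusted p = 0.811), nor did the permutation test with stricter peaks (0.505) or windows of 10 kb (1.0). HOXB3 (chromosome 17, 48548870 to 48590241) had 21.0 ± 0 regions under the NSC label and 0 ± 0 under the ESC label, and HOXA3 (chromosome 7, 27107010 to 27152583) had 22.5 ± 2.12 and 2.0 ± 1.41 (SD, n = 2). HOXD1 had 5 NSC-only regions and HOXB13 had 4, with 0 ESC-only regions at either.

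Loci of the other regional and lineage lists did not pass by the permutation test. With all peaks, the central 95% of random lists reached 100% for each of these lists. None of them could therefore pass toward the NSC label in that setting. Forebrain loci had 81 NSC-only and 1 ESC-only regions (adjusted p = 0.938), with 9 and 0 at EMX1, 10 and 0 at SIX3, 3 and 0 at NKX2-1 and 2 and 0 at SIX6; without ESC replicate 1 this list passed (0.00600). Midbrain to spinal cord loci had 174 and 3 (0.938), with 17 and 0 at PAX2, 15 and 0 at PAX7, 3 and 0 at EN2 and 3 and 1 at IRX5. Neuronal loci had 140 and 4 (0.826), including 13 and 0 at RBFOX3, which encodes NeuN, 11 and 0 at NEUROG1, 2 and 0 at ISL1 and 0 and 1 at ELAVL4. Without ESC replicate 2 the neuronal list passed in the opposite direction, 7.21 points above the random median (adjusted p = 0.0190). Glial loci had 83 and 1 (0.938), including 12 and 0 at MBP, 10 and 0 at ALDH1L1 and 2 and 0 at both AQP4 and S100B. Neural crest and mesenchyme loci had 111 and 2 (0.938), including 10 and 0 at TFAP2A, 9 and 0 at PAX3 and 2 and 0 at both SNAI2 and LUM. Endoderm and mesoderm loci had 102 and 0 (0.679), including 12 and 0 at SOX17, 11 and 0 at GATA4, 3 and 0 at AFP and 2 and 0 at MIXL1.

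Among signalling, adhesion and reference lists, Notch loci had 135 NSC-only and 4 ESC-only regions (adjusted p = 0.857, permutation test), with 11 and 0 at both HEYL and RFNG, 3 and 1 at MAML2 and 2 and 0 at HEY1. Loci of FGF, TGF-beta and Hedgehog signalling had 197 and 6 (0.737), with 12 and 0 at GLI2, 11 and 0 at FGFR1, 2 and 1 at FGFR3 and 1 and 0 at SPRY2. With equal numbers of peaks both lists passed toward the ESC label, Notch with 31 and 18 regions (adjusted p = 0.0486) and the signalling list with 52 and 28 (0.0307), but neither passed Fisher's exact test, two-sided, on distinct regions (adjusted p = 0.108 and 0.0938). Adhesion loci had 146 and 5 (0.737), including 10 and 0 at CLDN6 and 2 and 0 at NCAM2, and genes shared by both cell types had 50 and 3 (0.670), including 7 and 0 at LIN28A, 2 and 0 at SALL1 and 5 and 1 at ZIC2. Housekeeping loci had 110 and 1 (0.857), including 9 and 0 at POLR2A, 7 and 0 at RPL13A, 1 and 0 at GUSB and 0 and 0 at VPS29. For Notch, adhesion, shared and housekeeping loci the central 95% of random lists also reached 100% with all peaks. These lists too could not pass toward the NSC label in that setting. Apart from WNT7B, no member of any list was called, either over all genes or adjusted over the list alone.

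**Figure D2:**
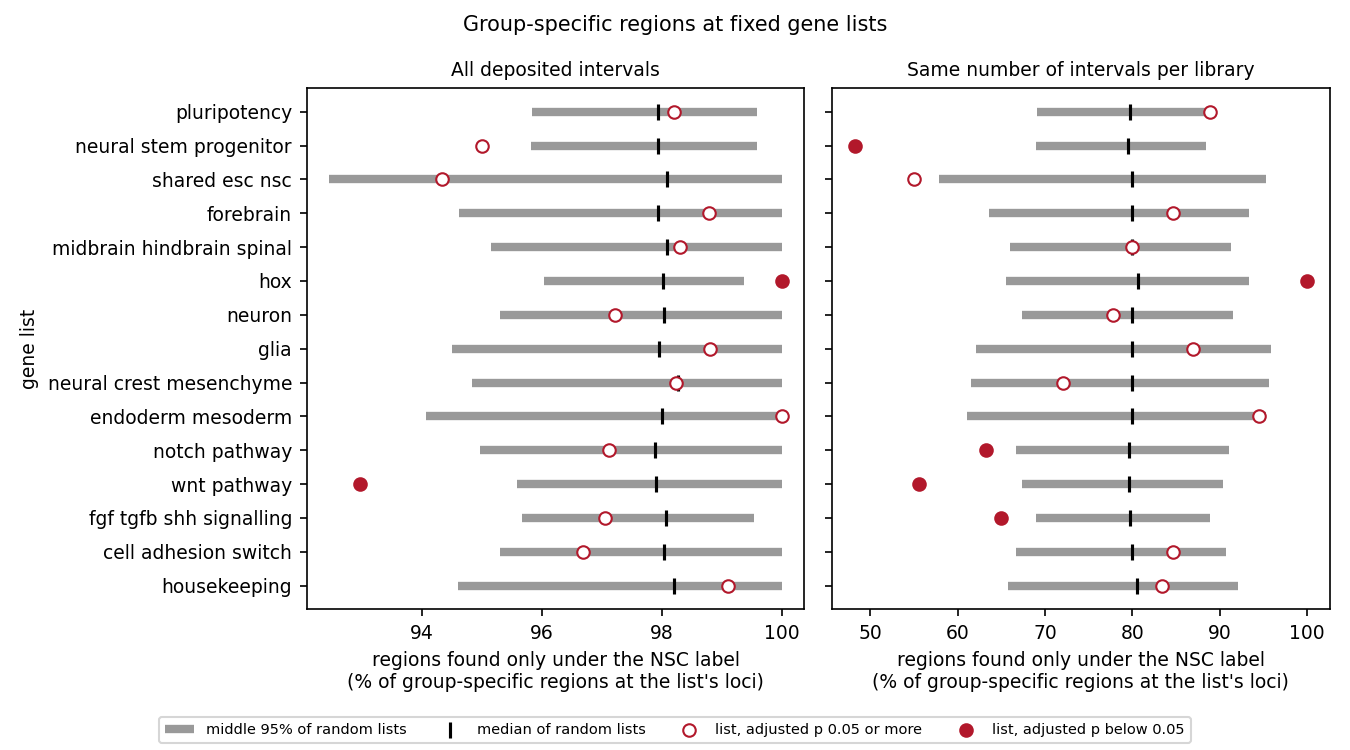
Share of NSC-only regions among the label-specific regions at the loci of each of 15 gene lists, in percent, with all deposited intervals on the left and equal numbers per library on the right, on different scales. Grey bars span the central 95% of 10000 matched random lists, ticks mark their median and filled circles mark lists with an adjusted p below 0.05; neural stem and progenitor loci lay at 95% on the left and 48.2% on the right.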

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

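Chosen only after the data were seen were the tests on distinct regions and those on the whole gene interval with 50 kb on both sides. With equal numbers of peaks there were 15585 NSC-only and 4897 ESC-only regions, a Jaccard difference of 0.246, context differences (labelled NSC minus labelled ESC) of -3.33 points at gene ends, -0.475 inside genes and 3.81 in intergenic regions, and 5 list-locus tests passed. ESC-only gene ends, 0 with all peaks, then passed at 12.2 points above other genes for neural stem and progenitor genes and 16.5 for Notch genes, and NSC-only gene ends lost their calls for midbrain to spinal cord and HOX genes, with 0 members left and -4.40 points for both. The neural and Notch genes behind the ESC-only calls had a gene-end peak in all 4 libraries with all peaks. With stricter peaks the ratio of intervals was 5.51, the Jaccard difference 0.373, ESC-only regions 1256, the difference inside genes -1.73 points, and 1 list-locus test passed. Reciprocal overlap gave 5355 ESC-only and 8242 common regions, gene ends of 2500 bp gave -1.18 points inside genes, windows of 10 kb left 0 list-locus tests, and distinct regions with Fisher's exact test left 1. Apart from the smaller numbers of peaks or the narrower windows that these settings use, the cause was not tested. Leaving out each library gave summit ratios of 3.47 to 3.82, Jaccard differences of 0.172 to 0.422, 78343 to 115616 NSC-only, 2631 to 17399 ESC-only and 16009 to 23311 common regions, differences inside genes of -0.846 to 0.80 points, and 0 to 3 genes called toward the ESC label; the wide ranges of label-specific regions follow from asking 1 library of a label in place of 2. Without ESC replicate 2, neuronal loci reversed to 7.21 points above the random median (-1.02 without NSC replicate 2, the lowest of the values with a library left out), and the cause was not tested. When at least 50% of an interval had to be covered, NSC replicates 1 and 2 and ESC replicates 1 and 2 overlapped 98.6%, 99.0%, 12.2% and 18.4% of the set named for ESC, and NSC replicates 1 and 2 and ESC replicate 2 overlapped 83.8%, 83.8% and 93.1% of the set named for NSC, as a stricter overlap must lower. With replicate number as a block, the per-gene test on all peaks, over the same 10234 genes, called 0 in either direction, as without it. That test gave 288 genes toward the NSC label and 174 toward the ESC label at an unadjusted p under 0.05. With no calls to lose, the block says nothing about stability. Same-numbered libraries did not deviate together in the presence of peaks (r = -0.000166 over 211047 regions). Whether they shared a batch is unknown. Of 135 alternative values for list loci, 119 kept their side of the threshold, 28 of them with the opposite sign, while 6 lost and 9 gained a call with their sign kept and 1 gained a call with the opposite sign. Of 240 for list gene ends, 220 kept their side, 16 of them with the opposite sign, while 10 lost and 6 gained a call with their sign kept and 4 changed both sign and side, 2 losing and 2 gaining a call. Of 737 for named loci, none was called, and 144 had the opposite sign. Motif alternatives were not run, since no genome sequence was used here. Depth is unknown, so weak peaks missed in the libraries labelled ESC limit every count of NSC-only regions.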

Other observations

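The test of exchanged labels was chosen only after its result was seen, and the genes named in the next paragraph were chosen after their values were seen.

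The loci with the most NSC-only regions held genes outside the fixed lists. GRM4, a metabotropic glutamate receptor gene (chromosome 6, 34018643 to 34155622), had 23 NSC-only and 0 ESC-only regions, with 29.5 ± 0.707 regions per library under the NSC label and 1.0 ± 0 under the ESC label (SD, n = 2). ANO1, a calcium-activated chloride channel gene (chromosome 11, 69965997 to 70189530), had 21 and 0, with 29.0 ± 2.83 and 1.5 ± 0.707 regions per library, and KRT80, an epithelial keratin gene (chromosome 12, 52168996 to 52192014), had 21 and 0, with 23.5 ± 0.707 and 1.0 ± 0 (n = 2 each). Toward the ESC label, LITAF (chromosome 16, 11547722 to 11640317) had 7 NSC-only and 4 ESC-only regions (p = 0.000178, adjusted p = 0.616) and ATXN10, next to WNT7B on chromosome 22, had 8 and 4 (p = 0.000261, adjusted p = 0.616), both by Fisher's exact test, two-sided, and neither passed. NR2F1, a nuclear receptor of neural progenitors, had 8 and 3 (p = 0.00312, adjusted p = 1.0 by the same exact test).

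By their untested shares, the pluripotency list and the neural stem and progenitor list went against the labels of the samples. With all peaks, neither list passed the permutation test at its loci (adjusted p = 0.938 and 0.0590). With equal numbers the neural list passed it (adjusted p = 0.00300). At gene ends with all peaks, the pluripotency list alone of these passed (adjusted p = 0.00269, Fisher's exact test, two-sided). When peak numbers were equal, both lists passed that test at gene ends, in opposite directions. Of the pluripotency genes, 8 of 33 were NSC-only (adjusted p = 0.00210), and of the neural genes 5 of 34 were ESC-only (0.0173). Those 5 neural genes had a gene-end peak in all 4 libraries with all peaks. Single genes overlapped, with ratios of mean region numbers, NSC label over ESC label, of 3.38 at LIN28B, 5.0 at DPPA4, 11 at POU5F1, 19 at NANOG and 24 at L1TD1. They were 1.71 at SOX1, 1.91 at POU3F2, 3.43 at PAX6, 3.5 at FABP7 and 8.33 at LHX2, and 3.58 over all merged regions. A lower number of peaks in the libraries labelled ESC, acting alike at every locus, is argued against. With equal numbers, the ratio of regions (NSC label over ESC label) at pluripotency loci was 2.16 times that at neural stem and progenitor loci. That setting keeps only the strongest intervals of the longer lists, so a loss that varies with peak strength was not tested. An exchange of the labels between the groups stays open as a candidate explanation: the log2 ratio of shares was 0.60 higher for pluripotency than for neural loci, which restates the pattern and cannot bear it out, and with all peaks the housekeeping ratio (0.578) lay below the neural one (0.761), and only with equal numbers of peaks did the neural ratio (0.729) lie below it (1.09). Shares at forebrain (ratio 1.3), midbrain to spinal cord (1.40), neuronal (0.985) and glial loci (1.07) give it no support, and reach 1.46, 1.31, 1.36 and 1.32 with equal numbers of peaks. The deposited interval sets, whose names match the names inside the peak lists and not the titles, leave open whether the titles or the files carry the wrong name.

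The libraries labelled NSC had many more peaks. A mean of 69.4% of the strongest 10% of intervals labelled NSC overlapped a peak labelled ESC, under the 90% set in advance as the bound. This argues against lower sensitivity in the libraries labelled ESC as the only difference between the labels. It cannot decide the cause of the difference in number, since peaks specific to a cell type lower the overlap at any sensitivity. A difference in accessible chromatin between the cell types is consistent with the 11.7% of reproducible regions labelled ESC that had no peak in either library labelled NSC, 2179 regions against 601 to 817 for pairs that mix the labels. Of the strongest 10% of intervals labelled ESC, 95.2% and 96.4% overlapped a peak labelled NSC, so few of the strong ones were specific to that label. Lower sensitivity in the libraries labelled ESC, from depth or background, could therefore still account for part or all of the difference in number, and depth is unknown.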
